A study of Mus musculus with 18 samples.

How the data were processed

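The series measured pancreatic and gut mesenchyme of mouse embryos at embryonic day 13.5 in which Eed, a core subunit of Polycomb repressive complex 2 (PRC2), had been deleted with a Cre recombinase expressed from the Bapx1 (Nkx3-2) locus, and compared it with Cre-carrying controls. Bulk RNA sequencing covered 2 control and 2 knockout libraries of pancreatic mesenchyme. Chromatin accessibility (Omni-ATAC, a transposase assay that marks open chromatin) covered 12 libraries, with 2 per genotype from pancreas, intestine and stomach mesenchyme. The intestine and stomach libraries were re-analysed by the authors from an earlier series, so organ and batch cannot be told apart where pancreas is compared with another organ. Single-cell RNA sequencing with a droplet kit covered whole pancreas, with 1 library per genotype. The labels describe sorting of live cells with a dead-cell stain and state no other gate, and no batch or pairing of replicates is stated.

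Per the labels, the authors used bcl2fastq 2.17, Trimmomatic 0.32, BWA 0.7.8, STAR 2.5.1b, MACS2 2.1.2, featureCounts and Cell Ranger with the mm10 genome build, without stating which tool served which assay. The deposited bulk RNA files hold raw counts per gene symbol, with the spike-in sequences of the library kit included and no normalization. The deposited ATAC table holds raw counts for 181218 regions shared by the 12 libraries, and how these regions were chosen is not stated. The deposited peak lists, 1 per genotype for pancreas with both replicates pooled, give fold enrichment over background together with -log10 p and -log10 q values of the peak caller. The smallest -log10 q was 1.01. The deposited single-cell matrices hold UMI counts per gene and barcode for barcodes that had already been filtered, and per the file headers were written by software version 3.0.2. Duplicate removal, strand setting and the gene annotation behind the counts are not stated.

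Genes and regions were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, TMM scaling and the default filter on low counts, two-sided, at an adjusted p (Benjamini-Hochberg) of 0.05. Of 43280 genes in the RNA files, 15707 were tested, and of the ATAC regions 172790 were tested. The 12 ATAC libraries were fitted in 1 model of 6 groups. It gave the knockout effect within each organ, the differences between control organs, and the difference of the knockout effect between organs. Fold changes are knockout over control unless stated. Levels are library-scaled counts (CPM), as means of 2 libraries with their SD. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, a ratio of summed counts with a 95% counting interval is given. Intervals and floors cover counting error only. Gene positions come from the RefSeq table, which gives no strand, so a region was assigned to a gene when it lay within the gene span or 1 kb of it, in place of the transcription start site that had been planned. No genome sequence was used here. The smallest total of an RNA library was 30077513 counts and of an ATAC library 10836570 counts.

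Before the data were examined, 28 gene lists, 11 cell type marker lists, the tests, the alternatives and the rule for naming genes were fixed. The gene lists were PRC2 subunits, each Hox cluster, posterior Hox genes, anterior Hox genes, transcription factors of other lineages, pancreatic and splenic mesenchyme transcription factors, cyclin-dependent kinase inhibitors, proliferation genes, Wnt ligands, Wnt antagonists and feedback targets, fibroblast growth factors, BMP and TGF-beta ligands and antagonists, the Hedgehog pathway, the retinoic acid pathway, extracellular matrix, markers of smooth muscle and mural cells, mesothelium, pancreatic epithelium, endocrine cells, gut epithelium and gut identity, endothelium, immune cells, erythroid cells and neural crest, neurons and glia, and dissociation stress genes. The rule named Eed, then the 10 largest rises and the 10 largest falls past the threshold with at least 5 CPM in the higher group and no overlap between genotypes, leaving out predicted genes and reporter sequences, then up to 4 members of each list with the smallest adjusted p. For ATAC it named the 5 regions per organ and direction with the smallest p at least 50 kb apart, and regions in Hox clusters or at genes named by the RNA rule. For single cells it named the 10 largest and 10 smallest ratios per cell class among genes with at least 50 counts in a library, and up to 4 members of each list with the most counts. List tests used camera of limma 3.58.1 with a preset correlation between genes of 0.01, beside an estimated correlation, and fry, each adjusted over the 28 lists. Counts of list members are given after adjustment over all tested genes and adjusted over the list alone. Sharing of genes between RNA and ATAC was described with Fisher's exact test, two-sided, across genes.

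Single cells were processed in Python 3.11.15 with scanpy 1.11.5. Cells with at least 1000 detected genes and under 10% mitochondrial counts were kept after removal of doublets called by Scrublet, which left 2136 control and 1867 knockout cells. Leiden clustering (resolution 1) used 2000 variable genes, 30 principal components and 15 neighbours without correction between libraries. The 19 clusters were named from the marker lists, and all names are of cells that resemble a type. How clusters were scored against the markers was settled after the clusters had been seen, and endocrine progenitor-like cells were counted with endocrine-like cells. Shares of cells carry exact Clopper-Pearson 95% intervals. Counts were summed per class and library for the 6 classes with at least 50 cells in each library, and ratios carry exact Poisson intervals. List medians were placed among 10000 random lists matched on expression. No test across libraries was possible with 1 library per genotype.

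The alternatives were other scalings (DESeq2 size factors, library totals, spike-in sequences), other filters, DESeq2 1.42.0 in place of edgeR, stricter thresholds, a replicate block, each library left out in turn, fits of single organs, autosomes only, other peak overlaps and q values, a wider gene window, and other cell filters, doublets kept, doubled resolution and thinned cells. Clustering without the genes that differed 2-fold between the libraries, and leaving out the first knockout library of each organ, were added after the data were seen. On simulated counts with the fitted spread, the RNA test recovered 68.7% of 2-fold and 94.0% of 4-fold changes with 10 unchanged genes called. The ATAC test recovered 20.9% of 2-fold and 61.2% of 4-fold changes with 5 unchanged regions called. The single-cell calculation returned a median log2 ratio of 1.91 for genes raised 4-fold. All files provided were used. Results for some named genes are not reported here. Chosen after values were seen were the genes whose share of cells with a UMI is given, the comparison within shared clusters, the region at Cdkn2b, and the comparison of organ-specific regions with matched regions.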

Results

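The data cover 18 libraries from mouse embryos, in which Eed was present or had been deleted in mesenchyme expressing Cre from the Bapx1 locus. Bulk RNA libraries of pancreatic mesenchyme held 37761315 and 35969521 counts in controls and 30077513 and 39728684 counts in knockouts. The 12 ATAC libraries held between 10836570 counts (stomach control replicate 2) and 16013165 counts (intestine knockout replicate 1) over the tested regions and those left out by the filter. Pancreas ATAC libraries held 10838144 and 11434442 counts in controls and 15585166 and 15831607 in knockouts. The single-cell libraries held 32999260 UMIs in 2225 barcodes of the control pancreas and 28921440 UMIs in 2026 barcodes of the knockout pancreas.

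The first comparison asked which transcripts differ in pancreatic mesenchyme after loss of Eed. Knockout mesenchyme expressed genes that controls left at or near 0, led by posterior Hox genes, transcription factors of other lineages and the cell cycle inhibitor Cdkn2a. Genes with a higher level outnumbered those with a lower level, 321 against 72 of 15707 tested genes (edgeR, 2 control and 2 knockout libraries). Eed itself (chromosome 7, 89954654 to 89980976) fell from 32.5 ± 1.45 to 7.15 ± 2.19 CPM (SD, n = 2), a log2 change of -2.19 (SE 0.23, adjusted p 0.0114). Among genes that fell were the cell adhesion gene Cdh7 and the collagen gene Col8a1.

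Hoxd13 (chromosome 2, 74668225 to 74671603), which patterns digits and the hindgut, had no counts in controls and 10.5 ± 0.152 CPM in knockouts, at least 255-fold higher (adjusted p 0.00279). Hoxb13 had no counts in controls and was at least 157-fold higher (6.32 ± 1.32 CPM, adjusted p 0.00467). Of 15 measured posterior Hox genes (paralogs 9 to 13), 12 rose over all genes tested and 15 rose adjusted over the list alone, with a median log2 change of 4.05. Hoxa10 went from 0.853 ± 0.226 to 14.7 ± 3.06 CPM (log2 change 4.11, SE 0.28, adjusted p 0.00419). Of 22 anterior Hox genes, 4 rose and 3 fell (9 and 9 adjusted over the list alone). The rise included Hoxa7 (2.61 on the log2 scale) and Hoxd8 (2.84), and the fall included Hoxb5, from 33.6 ± 2.62 to 11.2 ± 0.727 CPM (log2 change -1.58), and Hoxc5 (-1.32). By cluster, 5 of 11 HoxA genes, 3 of 10 HoxB genes, 3 of 8 HoxC genes and 5 of 8 HoxD genes rose, and 1 fell in each of HoxA, HoxB and HoxC (adjusted over the list alone, 7, 3, 6 and 8 rose, and 4, 4 and 1 fell outside HoxD). Camera placed HoxA (adjusted p 6.0e-11), HoxC (2.0e-06), HoxD (4.8e-36) and posterior Hox genes (7.6e-74) above other genes, and with an estimated correlation the adjusted p were 0.184, 0.175, 0.107 and 0.107. For HoxB and anterior Hox genes the median was negative (-0.31 and -0.13) while the mean (1.14 and 0.49) and the direction of camera were positive (adjusted p 0.351 and 0.570). With spike-in scaling the falls of Hoxb5 and Hoxc5 turned into rises of 0.49 and 0.79.

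**Figure D1:**
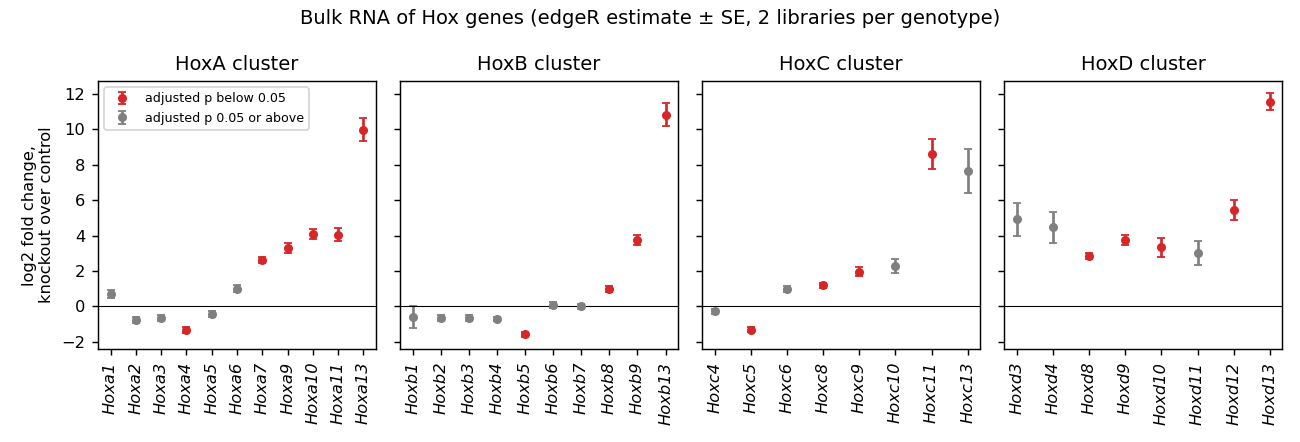
Log2 change of Hox genes in bulk RNA, knockout over control, by cluster and paralog number (edgeR estimate with SE, 2 libraries per genotype), with calls in red. Estimates of genes with no counts in controls, such as Hoxd13, depend on the fit. Hoxb5 and Hoxc5 were lower in knockouts, except with spike-in scaling.

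Of 87 transcription factors of other lineages, 53 were measured, and 26 rose (42 rose and 2 fell adjusted over the list alone). Their median log2 change was 3.08, or 3.06 with genes at 0 in controls set to their bound. Alx1, a factor of craniofacial mesenchyme, went from 0.178 to 10.3 ± 1.77 CPM (log2 change 5.82), and Tbx15 from 0.193 to 7.48 CPM (5.26). Shox2, a limb and heart factor, rose by 3.82 and Tbx20, a heart factor, by 3.66 on the log2 scale. Zic1, a neural factor, had no counts in controls and was at least 168-fold higher, and the eye factor Vax2, named by the rule on the largest rises, was at least 136-fold higher. Sall1 (6.01) and the cortical factor Tbr1 (4.46) rose in the same way. Camera gave an adjusted p of 4.0e-63 for this list, and 0.107 with an estimated correlation. Of 21 factors of pancreatic and splenic mesenchyme, 2 rose (6 rose and 1 fell adjusted over the list alone). Camera gave an adjusted p of 0.0802 for this list and fry 0.0362. The 2 that rose were Foxf2 (0.70 to 5.31 CPM, log2 change 2.92) and Foxf1 (12.6 to 27.8 CPM, 1.15). Barx1 changed by -0.64 (adjusted p 0.0972), and passed with DESeq2 (0.0159), no filter (0.00839), the replicate block (0.0131) and without knockout replicate 2 (0.031). Without control replicate 1, the adjusted p of Foxf1 was 0.159.

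Cdkn2a (chromosome 4, 89274473 to 89294619), which encodes the cell cycle inhibitor p16 and the p53 activator p19, had 1 count in controls and 1278 in knockouts, a ratio of 1332 (95% counting interval 239 to 52662), and reached 17.9 ± 3.43 CPM (adjusted p 0.00196). Its neighbour Cdkn2b went from 0.206 to 3.57 CPM (log2 change 4.10) and Cdkn2c from 14 to 33.3 CPM (1.25). Thus 3 of 7 cyclin-dependent kinase inhibitors rose (4 adjusted over the list alone; camera adjusted p 4.6e-10, and 0.123 with an estimated correlation). Cdkn1a changed by 1.32 with an adjusted p of 0.190, and passed with the replicate block (0.0295) and without knockout replicate 1 (0.0113). None of 25 proliferation genes passed the edgeR test, over all genes or adjusted over the list alone (1 rose and 4 fell at an unadjusted p, and DESeq2 called 0). Camera placed the list lower (adjusted p 0.00336, and 0.778 with an estimated correlation), at a median log2 change of -0.25, while fry gave an adjusted p of 0.451. Mki67 was uneven between the knockout libraries, with 17.5 and 102 CPM, and passed as a rise without knockout replicate 1 (2.95, adjusted p 2.49e-04). Without control replicate 1, the adjusted p of Cdkn2c was 0.114.

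Single signalling and matrix genes also changed. Wnt5a, a non-canonical Wnt ligand, fell from 203 ± 8.40 to 106 ± 7.83 CPM (log2 change -0.94, adjusted p 0.0198), the only call among 12 Wnt ligands (2 rose and 1 fell adjusted over the list alone). Bmp6 fell from 22.1 to 10.0 CPM (-1.14), the only change past the threshold among 23 BMP and TGF-beta genes (2 rose and 2 fell adjusted over the list alone). In the retinoic acid pathway the binding protein Crabp1 rose from 34.9 to 70.3 CPM (1.01), while Rdh10, which makes retinaldehyde, and Cyp26b1, which degrades retinoic acid, fell by 0.94 and 0.78 on the log2 scale (1 rose and 2 fell of 15; 4 and 3 adjusted over the list alone). Of 32 matrix genes, Postn, which encodes periostin, rose from 147 ± 19.3 to 413 ± 151 CPM (1.49, adjusted p 0.0480), also adjusted over the list alone. Of 15 smooth muscle and mural markers, Kcnj8 (-0.95) and Rgs5 (-0.99) fell (3 fell adjusted over the list alone). Foxf1 and Foxf2 were the 2 of 14 Hedgehog pathway genes that rose (3 adjusted over the list alone). With TMM scaling and the default filter of edgeR no gene passed among 20 Wnt antagonists and feedback targets (1 rose and 1 fell adjusted over the list alone, 2 and 1 at an unadjusted p, 2 and 1 with DESeq2) or 12 fibroblast growth factors (2 rose and 1 fell at an unadjusted p, 0 with DESeq2), and Sfrp2 changed by 1.11 (adjusted p 0.0568). Sfrp2 passed with library totals (0.0335), no filter (0.00754), the replicate block (0.0035), DESeq2 (1.17e-04) and without knockout replicate 1 (4.37e-04) or 2 (0.00567). Camera passed none of these lists (adjusted p 0.772 for Wnt ligands, 0.769 for Wnt antagonists, 0.920 for fibroblast growth factors, 0.430 for BMP and TGF-beta genes, 0.0765 for Hedgehog, 0.939 for retinoic acid, 0.0841 for matrix and 0.0802 for smooth muscle, where the median was positive and the test pointed down), except that the replicate block passed matrix genes (0.00546). Leaving out control replicate 1 or control replicate 2 ended the calls of Wnt5a, Bmp6, Crabp1, Rdh10, Cyp26b1, Postn and Kcnj8, with adjusted p from 0.0534 (Bmp6) to 0.319 (Cyp26b1). Rgs5 missed without control replicate 1 (0.121), and Postn also with DESeq2 size factors (0.0557) and with no filter (0.126). With spike-in scaling the falls of this paragraph turned into rises, such as 1.11 for Wnt5a.

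Markers of cell types other than mesenchyme also differed. Of 11 endothelial markers, 7 rose (9 adjusted over the list alone), with a median log2 change of 2.22 (camera adjusted p 1.7e-26, and 0.107 with an estimated correlation). Cdh5, the endothelial cadherin, went from 2.83 ± 0.223 to 20.8 ± 2.01 CPM (2.88, adjusted p 0.00279), and Pecam1 from 2.2 to 14.2 CPM. Among the 321 higher genes, 34 belonged to the 187 genes enriched in endothelium-like single cells (18.2%, against 2.04% of all genes), and 287 remained without them. The share was 9.78% for genes enriched in acinar-like, 8.33% in trunk-like, 8.25% in neural-like, 6.56% in immune-like, 4.03% in endocrine-like, 3.76% in erythroid-like and 1.61% in mesothelium-like cells. For mural-like cells it was 0 of 40 genes. Of 4 gut identity genes 3 rose (4 adjusted over the list alone; camera adjusted p 1.1e-11, and 0.107 with an estimated correlation), among them Sox2, with 2 counts in controls and 138 in knockouts (ratio 71.9, 19.5 to 600), and Onecut2 (2.67). Of 6 endocrine genes 1 rose (2 adjusted over the list alone; camera adjusted p 1.1e-04, and 0.180 with an estimated correlation). The complement gene C1qb, with 2 counts against 48 (ratio 25, 6.56 to 213), was the rise among 5 immune genes (3 rose and 1 fell adjusted over the list alone), and Fabp7 (-1.76) the fall among 8 neural genes (3 rose and 1 fell adjusted over the list alone). With edgeR no gene passed among 12 epithelial (1 rose adjusted over the list alone, 5 rose and 2 fell at an unadjusted p, 1 and 1 with DESeq2), 10 mesothelial (1 rose at an unadjusted p, 0 with DESeq2), 5 erythroid (4 fell adjusted over the list alone and at an unadjusted p, 1 with DESeq2) or 11 dissociation stress genes (0 at an unadjusted p, 0 with DESeq2). Camera placed the erythroid genes lower (adjusted p 9.99e-04, and 0.471 with an estimated correlation) and passed none of the immune (0.0909), neural (0.403), epithelial (0.230), mesothelial (0.447) and stress (0.939) lists. Of 11 PRC2 genes Eed was the only fall, also adjusted over the list alone, with Ezh2 at -0.22 and Jarid2 at 0.45 (camera adjusted p 0.0518, and 0.0385 with the replicate block). Leaving out control replicate 1 gave adjusted p of 0.114 for C1qb and 0.0534 for Fabp7, and C1qb also missed without control replicate 2 (0.0961) and with DESeq2 size factors (0.054).

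The 10 largest falls included Trim12a (-5.40), Eif3j2 (-4.89), the unplaced transcript RP23-349K15.2 (-6.30), Cdh7 (8.50 ± 0.0679 to 1.09 ± 0.206 CPM, -2.97), Col8a1 (143 ± 17 to 26.4 ± 7.04 CPM, -2.44, SE 0.21, adjusted p 0.00679) and Myo7a (-2.46). RP23-349K15.2 missed the threshold without knockout replicate 1 (adjusted p 0.11) or 2 (0.189), and Myo7a with DESeq2 size factors (0.0502), with no filter (0.0746) and without control replicate 2 (0.0925). At an unadjusted p the test counted 1684 higher and 620 lower genes. All 393 called genes had no overlap between genotypes, which follows in large part from choosing them by a test on the same libraries. The counts were 178 and 41 without control replicate 1, 226 and 41 without control replicate 2, 1252 and 292 without knockout replicate 1, and 519 and 321 without knockout replicate 2. Spike-in scaling, whose share of counts ranged from 0.0109% to 0.140% among libraries, moved the median of all genes by 2.07 on the log2 scale and left 15 genes called, all higher, while DESeq2 counted 665 and 182.

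The second comparison asked where chromatin accessibility differs in pancreatic mesenchyme after loss of Eed. Regions in the Hox clusters and at Cdkn2a and Cdkn2b were more accessible in knockouts. Over all 172790 tested regions, those with a loss outnumbered those with a gain, 1180 against 543, but with library totals the counts were 746 and 690, and without knockout replicate 1 gains outnumbered losses (298 and 190), while losses stayed ahead without the first knockout library of every organ (2350 and 3114), a fit added later. With edgeR no region of the 4 Hox clusters lost accessibility at the threshold (2 of 107 at an unadjusted p, 0 with DESeq2). Of regions at genes whose transcripts fell, 1 of 5 at Cdh7, 1 of 20 at Bmp6, 1 of 2 at Kcnj8 and 1 of 5 at Cyp26b1 lost accessibility. The median over the Cyp26b1 regions was positive (0.24). At other genes that fell edgeR called 0 lost, such as Wnt5a (5 regions), Rdh10 (3), Col8a1 (11), Myo7a (12), Rgs5 (9) and Hoxb5 (2).

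In the HoxD cluster (chromosome 2, 74668225 to 74765142) 8 of 21 regions were more accessible in knockout pancreas, with a median log2 change of 0.88. HoxC had 5 of 31 (0.73), HoxA 5 of 23 (0.36) and HoxB 4 of 32 (0.04). A region in Hoxd8 (chromosome 2, 74703851 to 74706118) went from 10.5 ± 2.13 to 23.0 ± 0.129 CPM (log2 change 1.13, adjusted p 0.00747). A region at Hoxa10 changed by 1.16 and a region at Hoxb9 by 1.12. Of 30 regions at posterior Hox genes 9 were gained, and of 51 at anterior Hox genes 9 were gained. Of 345 regions at transcription factors of other lineages 14 were gained, such as one at Alx1 (chromosome 10, 103026998 to 103031054, 10.6 ± 1.79 to 25.6 ± 2.36 CPM, 1.27, adjusted p 0.00135). At other genes with large RNA rises edgeR called 0 gained, namely Hoxd13 (1 region), Hoxb13 (1), Zic1 (2), Sall1 (3), Tbr1 (4) and Tbx15 (11). Their median log2 changes were positive, from 0.34 (Tbr1) to 0.89 (Hoxd13).

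**Figure D2:**
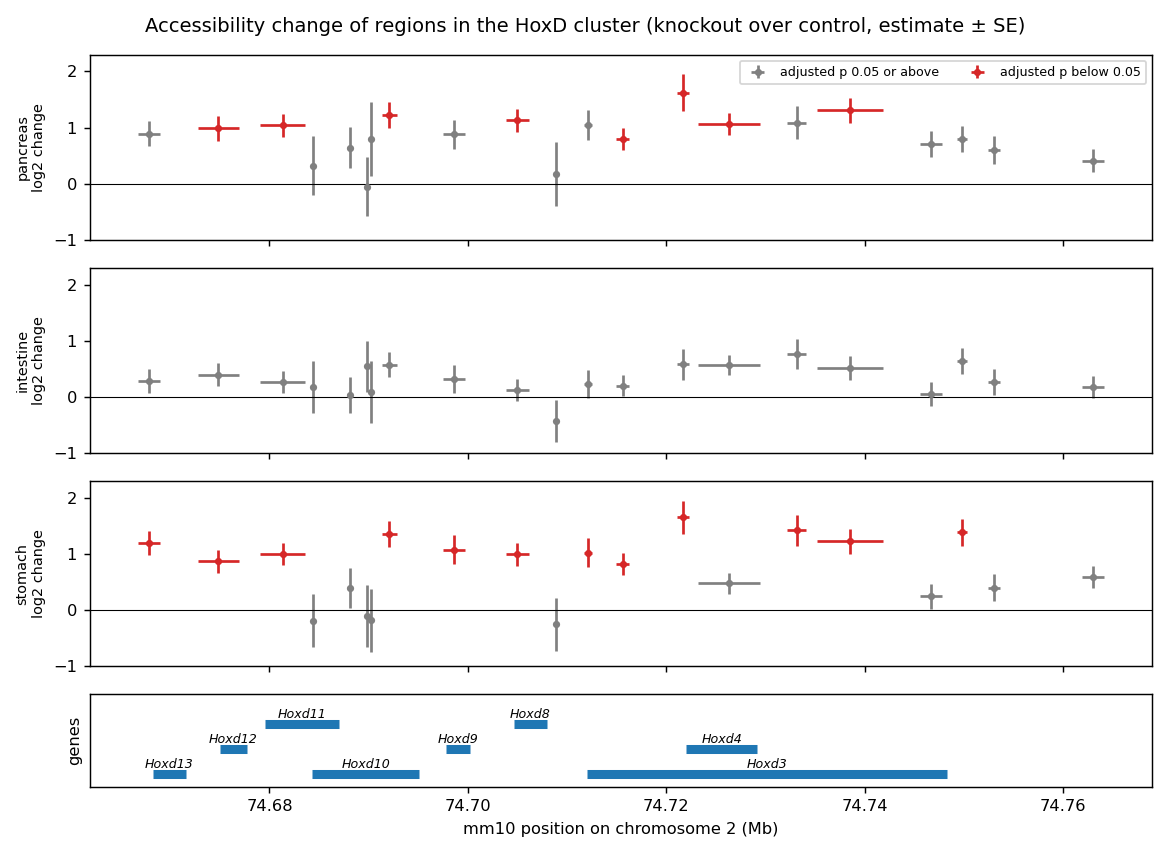
Log2 change of accessibility, knockout over control (edgeR estimate with SE), at each region along the HoxD cluster in pancreas, intestine and stomach mesenchyme, by position on chromosome 2. The median was 0.88 in pancreas, 0.87 in stomach and 0.26 in intestine.

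A region inside Cdkn2a (chromosome 4, 89281614 to 89283129) went from 3.88 ± 0.693 to 14.2 ± 2.70 CPM (1.87, adjusted p 0.0010), and a region at Cdkn2b (89310220 to 89311317) from 11.6 ± 0.243 to 28.7 ± 1.93 CPM (1.30, adjusted p 8.65e-04). Of 10 regions at cyclin-dependent kinase inhibitors 3 were gained. Losses included 1 region each at Cdh7 (-1.62), Bmp6 (-1.72), Cyp26b1 (-1.08), Kcnj8 (-1.02) and the PRC2 partner Aebp2 (-1.03). A region inside Postn was lost (-2.42) although its transcript rose. Matrix genes had 4 lost of 390 regions, mesenchymal transcription factors 2 lost of 197, and of 70 regions at endothelial genes edgeR called 0 (2 gained and 2 lost at an unadjusted p, 0 with DESeq2). Among regions with the smallest p were gains at chromosome 12, 20614805 to 20615762 (3.13), and chromosome 14, 50903815 to 50904595 (4.05, 6331 bp from Klhl33), and a loss at chromosome 5, 52506662 to 52507141 (-3.45, 26375 bp from Lgi2). At an unadjusted p 11013 regions were gained and 15263 lost. Leaving out single pancreas libraries gave 15 gained and 35 lost (control replicate 1), 28 and 37 (control replicate 2), 298 and 190 (knockout replicate 1) and 1168 and 2090 (knockout replicate 2). Of 38 called regions in Hox clusters and at named genes, 0 kept their call without control replicate 1, 3 without control replicate 2, 26 without knockout replicate 1 and 25 without knockout replicate 2, though all kept their direction. Without control replicate 1 the adjusted p was 0.0879 at Cdkn2a, 0.0574 at Cdkn2b, 0.105 at Alx1 and 0.208 at Hoxd8, and with DESeq2 the regions at Cdh7 (0.0821) and Bmp6 (0.0567) missed.

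The third comparison set the knockout effect in pancreas beside that in intestine and stomach mesenchyme. In stomach 1600 regions were gained and 2783 lost, and in intestine 204 were gained and 351 lost. Without knockout replicate 1 the balance turned, to 768 gains and 478 losses in stomach and 52 and 19 in intestine, while without the first knockout library of all organs losses stayed ahead (4214 and 4939, and 496 and 550). Pancreas and stomach shared 268 gains and 295 losses, where 5.03 and 19.0 would be shared by independent calls, and pancreas and intestine shared 97 and 65 (0.641 and 2.4). Gains in all 3 organs numbered 91 and losses 52. Of the regions gained in pancreas, 95.8% changed in the same direction in stomach and 94.3% in intestine. Of those lost in pancreas, 90.9% and 81.1% did, with a median of -0.81 in stomach and -0.43 in intestine against -1.49 in pancreas. The difference between knockout replicates 1 and 2 correlated between organs (0.28 to 0.39, against 0.03 to 0.07 in controls), which the value for independent calls leaves out.

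The Hox clusters gained accessibility in stomach at 5 HoxA, 5 HoxB, 13 HoxC and 12 HoxD regions, against 1 HoxB and 1 HoxC region in intestine. A region in Hoxc13 (chromosome 15, 102920615 to 102922301) gained 2.13 in stomach, 1.19 in pancreas and 1.05 in intestine on the log2 scale. The Cdkn2b region gained 1.66 in stomach and 1.34 in intestine, and the region inside Cdkn2a gained 2.57 in stomach. Regions at transcription factors of other lineages gained at 53 of 345 in stomach and 2 in intestine. Some of the regions with the smallest p had counts in knockouts alone in all 3 organs. The region in Gm2058 (chromosome 7, 39588508 to 39589328) had 0 counts in pancreas controls and 260 in knockouts (at least 58.3-fold higher, and at least 59.3-fold in intestine and 67.2-fold in stomach). Whether such an absence of counts reflects closed chromatin or a variant of the sequence was not tested. A region in Cwc27 (chromosome 13, 104742974 to 104743134) was lower by -5.01, -5.16 and -4.84 in pancreas, intestine and stomach. No region passed a test of the difference in knockout effect between organs with edgeR. At an unadjusted p 4286 and 6703 regions had a higher and a lower effect in pancreas than in intestine, 5462 and 4858 than in stomach, and 5346 and 2846 differed between intestine and stomach, and DESeq2 called 0, 0 and 1. Leaving out a library moved the stomach counts to between 39 and 1629 gains and the intestine counts to between 15 and 1078. Of the called regions in Hox clusters and at named genes 5 of 59 in stomach and 1 of 5 in intestine kept their call without control replicate 1. With library totals the balance in intestine turned to 308 gains over 232 losses.

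The fourth comparison asked how accessibility differs between control organs and whether the knockout pancreas moves toward another organ. Control pancreas differed from intestine at 36011 regions (21049 higher and 14962 lower in pancreas) and from stomach at 34804 (19676 and 15128), while control intestine and stomach differed at 3529 (1309 higher in intestine and 2220 lower). Regions higher in control pancreas than in both other organs (13459) lost accessibility in knockout pancreas, with a median log2 change of -0.44, against -0.10 in simulations without a knockout effect and 0.03 in other regions of matched level. Of these, 587 were lost and 17 gained at the threshold. The control pancreas libraries both chose these regions and served as the baseline, so the choice alone gives a fall. The simulations called 6983 to 7380 regions higher in intestine than in stomach, against 1309 in the data. They do not match the data there, so their -0.10 may not bound the part due to the choice. Regions lower in control pancreas than in both other organs (8255) changed by 0.26, where the simulations reached 0.23 to 0.25. Regions higher in intestine than in stomach changed by -0.17 in knockout pancreas and regions higher in stomach by -0.19, so neither set rose. The pancreas-high regions changed by -0.57 in knockout replicate 1 and -0.31 in knockout replicate 2. Pancreas libraries come from another series than the other organs, so their organ differences cannot be told apart from batch, and leaving out a library lowered the counts to between 18011 and 20994, 16376 and 19867, and 172 and 525 regions.

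The peak lists asked the same question as the region table with no replicates. The control list held 123355 peaks over 87.6 Mb and the knockout list 129286 peaks over 100 Mb, from fewer counts in controls. Overlap of at least 1 bp was found for 85.5% of control and 81.0% of knockout peaks. In the HoxD cluster peaks covered 21678 bp in controls and 34103 bp in knockouts. Covered length in the other clusters went from 30947 to 38834 bp (HoxA), 33880 to 42392 bp (HoxB) and 28438 to 34520 bp (HoxC). Peaks found in 1 list alone were narrower (median 239 bp in controls and 259 bp in knockouts) and had lower enrichment (2.89 and 2.74) than shared ones (4.33 and 4.11).

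RNA and accessibility changed at the same genes more often than separate draws would give. Of 303 higher genes with a tested region within the gene or 1 kb of it, 43 (14.2%) had a gained region, against 1.5% of all 13963 genes (odds ratio 13.4, 95% interval 9.17 to 19.4, Fisher's exact adjusted p 3.5e-29). Of 57 lower genes 7 had a lost region (odds ratio 3.83, 1.46 to 8.55, Fisher's exact adjusted p 0.00944). Higher genes with a lost region numbered 6, where 10.8 would arise by separate draws, and none of the 57 lower genes had a gained region (upper bound of the odds ratio 4.42). Genes are not independent replicates, and at an adjusted p of 0.01 no lower gene had a lost region, with 6 lower genes left.

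The single-cell libraries asked which cells of the pancreas differ after loss of Eed in mesenchyme, with 1 library per genotype and so no replicate error. Mesenchyme-like cells made up 67.8% of control cells (exact interval 65.8 to 69.8) and 65.3% of knockout cells (63.1 to 67.5). Endocrine-like cells made up 1.87% (1.34 to 2.54, 40 of 2136 cells) and 4.71% (3.80 to 5.78, 88 of 1867 cells). Among epithelium-like cells alone, endocrine-like cells made up 12.8% (9.29 to 17) in the control and 28.9% (23.8 to 34.3) in the knockout. Progenitor or trunk-like cells made up 50.5% (44.8 to 56.2) and 34.8% (29.4 to 40.4), and acinar or tip-like cells 36.7% and 36.4%. Intervals of the other classes overlapped between libraries: mesothelium-like cells made up 7.91% and 8.52%, immune-like 2.76% and 3.75%, neural-like 2.72% and 2.95%, mural-like 2.81% and 1.98%, endothelium-like 1.22% and 0.857%, and erythroid-like 3 and 6 cells. Over 4 alternatives the share of endocrine-like cells among epithelium-like cells ran from 13.1% to 17.3% in the control and from 28.6% to 32.4% in the knockout.

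**Figure D3:**
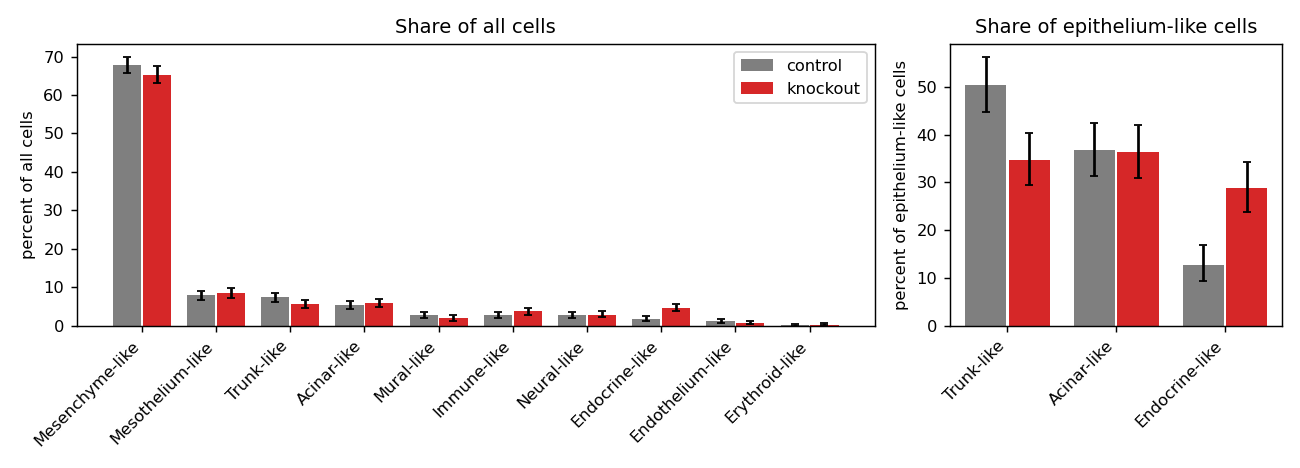
Share of each cell class among all cells and among epithelium-like cells in the control and knockout single-cell libraries, in percent, with exact 95% intervals. Endocrine-like cells went from 12.8% to 28.9% of epithelium-like cells.

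Within mesenchyme-like cells, Cdkn2a and posterior Hox genes were again seen in the knockout and nearly absent from the control. Cdkn2a had 2 UMIs (0.108 CPM) in 1448 control cells and 1161 (76.5 CPM) in 1219 knockout cells, a ratio of 707 (195 to 5842). Hoxa10 had 0 and 178 UMIs (at least 72.2-fold higher), Vax2 0 and 154 (at least 62.5-fold), and Hoxa7 83 and 1025. Hoxb5 went from 68.5 to 16.5 CPM and Hoxb4 from 137 to 52.3 CPM. Several clusters of mesenchyme-like cells held 1 genotype almost alone, such as 586 control and 8 knockout cells in the largest.

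Posterior Hox genes had a median log2 ratio of 3.30 over the 5 of 16 members with enough counts, above every one of 10000 matched random lists. Anterior Hox genes had -0.26 (percentile 0.03). Transcription factors of other lineages had a median of 1.49, with 12 of 15 higher, and cyclin-dependent kinase inhibitors 1.31. Members needed at least 50 counts in either library. A gene near 0 in the control could enter only by being high in the knockout, so for such lists the filter itself favours a rise. Of 25 proliferation genes 3 were higher, with a median of -0.39, below all random lists. Neural-like cells moved the same way, with 1 of 23 higher and a median of -0.31, also below all random lists. Medians were positive in acinar-like (0.06), trunk-like (0.18) and immune-like cells (0.17). Ube2c went from 188 to 106 CPM and Top2a from 151 to 109 CPM. Of 32 matrix genes 29 were higher, with a median of 0.54, and Postn went from 24.5 to 105 CPM. Sfrp2 went from 78.7 to 276 CPM, Crabp1 from 56.2 to 222 CPM and Wnt5a from 58.8 to 19.8 CPM. Eed went from 29.1 to 21.9 CPM. Of 124 genes higher in bulk RNA and measured here 123 were higher, and of 50 lower genes 49 were lower.

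In knockout mesenchyme-like cells 32.3% had a Cdkn2a UMI, against 0.138% of control cells, and in knockout mesothelium-like cells 39.6%, against 0 of 169 control cells (upper limit 2.16%). At 5000 UMIs per cell the knockout shares were 20.8% and 26.9%. Of knockout mural-like cells 37.8% had a Cdkn2a UMI. In knockout neural-like cells 0 of 55 cells had a UMI (upper limit 6.49%) at a median of 14673 UMIs per cell, against 11809 in mesenchyme-like cells. Of acinar-like and trunk-like knockout cells 2.70% and 4.72% had a UMI, and at these cell numbers a difference from the neural-like share was not detectable. In mesothelium-like cells Cdkn2a reached 95.1 CPM, and Hoxb9 had 1 and 80 UMIs (ratio 87.7, 15.3 to 3510).

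**Figure D4:**
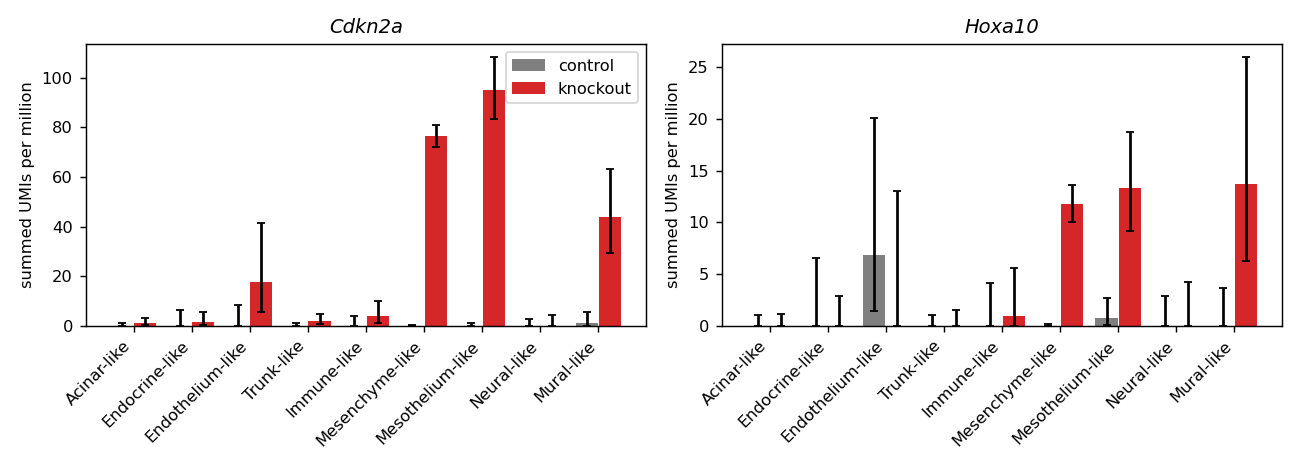
Level of Cdkn2a and Hoxa10 per cell class in the control and knockout single-cell libraries, as CPM of summed UMIs with exact 95% counting intervals. Knockout mesenchyme-like cells reached 76.5 CPM and mesothelium-like cells 95.1 CPM of Cdkn2a.

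In acinar-like cells the digestive enzyme genes Ctrc (14 and 162 UMIs, ratio 12.2, 7.08 to 22.9) and Cela2a (9 and 68 UMIs, 7.98) were higher in the knockout, and the glucose transporter gene Slc2a2 (104 and 17 UMIs) and the progenitor factor Sox11 (135 and 32 UMIs) were lower. Trunk-like cells had more Ctrb1 (12 and 67 UMIs) and less of the Notch ligand gene Dll1 (74 and 16 UMIs) and of Rbp4 (246 and 52 UMIs). Pancreatic epithelium markers had a median log2 ratio of 0.53 in acinar-like and 0.42 in trunk-like cells. They were also higher in mesenchyme-like (0.74, 7 of 9 genes) and mesothelium-like cells (0.43, 3 of 4), so the rise was not confined to epithelium-like cells. Erythroid markers had medians from 1.34 to 2.12 in every class compared. Whether such counts arose in the cells themselves was not tested. In immune-like cells the mast cell genes Cma1 (7 and 618 UMIs) and Tpsb2 (8 and 283 UMIs) were higher while the mast cell gene Cpa3 (403 and 91 UMIs) was lower, as was Mpo (64 and 0 UMIs, at least 23.9-fold lower). Neural-like cells had less Gal (56 and 1 UMIs) and Cck (432 and 86 UMIs). In all classes Xist was found in the control library alone apart from 1 or 2 UMIs per class, and Ddx3y and Eif2s3y in the knockout library alone, so that sex differs with genotype between these libraries. Dissociation stress genes were higher in every class compared, with median log2 ratios from 0.23 in immune-like to 1.09 in trunk-like cells.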

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

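Tests without the first knockout library of each organ, and clustering without genes that differed between libraries, were chosen after the data were seen. All other alternatives were planned.

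For bulk RNA, the 321 higher and 72 lower genes became 665 and 182 with DESeq2, 781 and 195 with no filter, 794 and 212 with a replicate block, 66 and 13 at an adjusted p of 0.01, and 15 and 0 with spike-in scaling. Leaving out 1 library gave 178 to 1252 higher and 41 to 321 lower genes, with the lone sample of an arm assumed to vary like the other group. The labels do not state that replicate numbers pair samples, and do not exclude it. The deviations of replicate 1 in controls and knockouts correlated at 0.28, so the block may absorb a shared batch or chance differences. Spike-in scaling moved the median of all genes by 2.07 on the log2 scale, and falls relative to other genes became rises: Myo7a 0.033, Fam20a 0.090, Hoxb5 0.49, Hoxc5 0.79, Wnt5a 1.11, Bmp6 1.01, Rdh10 1.03, Cyp26b1 1.27, Kcnj8 1.05, Rgs5 1.02, Fabp7 0.13, and, among genes that had missed the threshold, Aebp2 1.79, Ezh2 1.85, Barx1 1.56 and Ube2c 1.77. The construction of that scaling shows the cause of these turns, whereas for the counts the cause was not tested, apart from the stricter threshold. The change of Eed lay between -2.54 and -1.91 over 10 alternatives and was -0.31 with spike-in scaling. Of 65 named genes, 15 kept their direction but missed the threshold without control replicate 1, 11 without control replicate 2, 1 without each knockout library, 3 with DESeq2 size factors in edgeR, 2 with no filter and 39 with spike-in scaling. With DESeq2 or the replicate block, 63 and 62 stayed on their side and the others newly passed. Of 28 gene lists, 11 passed camera, 0 with an estimated correlation between genes, and 13 with the replicate block, which added matrix genes (adjusted p 0.00546) and PRC2 genes (0.0385). Of the lists that passed camera, proliferation (fry adjusted p 0.451), erythroid (0.254) and endocrine genes (0.0711) missed with fry, and the others passed. Fry also passed pancreatic and splenic mesenchyme transcription factors (0.0362). With 2 against 2 libraries, simulated counts gave a recovery of 68.7% for 2-fold changes.

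For ATAC of pancreas, the 543 gains and 1180 losses became 1121 and 2122 in a fit of that organ alone, 327 and 631 with DESeq2, 821 and 1820 with the replicate block, 92 and 176 at an adjusted p of 0.01, 2350 and 3114 without the first knockout library of each organ, and 15 to 1168 and 35 to 2090 without 1 library, and library totals gave 690 gains and 746 losses. The 204 gains and 351 losses of intestine became 1054 and 1836 in a fit of that organ alone, 308 and 232 with library totals, 470 and 972 with the replicate block, 54 and 37 at an adjusted p of 0.01, 496 and 550 without the first knockout library of each organ, and 15 to 1078 and 17 to 2337 without 1 library. With library totals the median of all intestine regions was 0.12, against 0.02 as reported. The balance of gains and losses turned to gains without knockout replicate 1 in each organ (298 and 190 in pancreas, 52 and 19 in intestine, 768 and 478 in stomach), and in intestine also at an adjusted p of 0.01 and with library totals. The 1600 gains and 2783 losses of stomach became 324 and 474 at an adjusted p of 0.01, 4214 and 4939 without the first knockout library of each organ, and 39 to 1629 and 53 to 3341 without 1 library, and DESeq2 gave 1564 losses. The regions with the smallest p (5 per organ and direction) gave 30 results, in which some regions count for more than 1 organ. All 30 results kept their direction and call with DESeq2, its size factors, library totals, no filter, autosomes alone, single-organ fits, the block and each library of their organ left out. Without the first knockout library of each organ 27 of the results did. Regions picked for the smallest p are the most likely to hold. Further called regions in Hox clusters and at named genes kept their direction throughout, but with 1 library left out their calls held for 0 to 26 of 38 in pancreas, 0 to 4 of 5 in intestine and 5 to 46 of 59 in stomach. With DESeq2 33 of 37, 5 of 5 and 57 of 59 held, and with library totals 34 of 38, 5 of 5 and 58 of 59. The cause of the changed counts was not tested beyond the smaller number of libraries and the stricter threshold. Simulated counts gave a recovery of 20.9% for 2-fold changes, so depth and replicates leave most small changes uncalled.

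Between control organs, 36011 regions (pancreas and intestine) became 23306 with DESeq2, 19544 at an adjusted p of 0.01 and 18011 to 20994 without 1 library. For pancreas and stomach, 34804 became 22293, 18630 and 16376 to 19867, and for intestine and stomach 3529 became 1888, 937 and 172 to 525, with 14126 without the first knockout library of each organ. No region had a knockout effect that differed between organs with edgeR. At an unadjusted p, which regions without any difference also meet, 4286 and 6703 had a higher and a lower estimate in pancreas than in intestine. Without the first knockout library of each organ there were 95 (pancreas and intestine), 99 (pancreas and stomach) and 107 (intestine and stomach), leaving out 1 library gave 0 to 3, 0 to 6 and 0 to 3, and for intestine and stomach DESeq2 and library totals each gave 1. In knockout pancreas the median change of intestine-high regions was -0.10 with library totals (-0.17 as reported), that of stomach-high regions -0.12 (-0.19 as reported), and that of pancreas-low regions 0.12 without the first knockout library of each organ (0.26 as reported). Here the cause was not tested. For lower genes with a lost region the odds ratio of 3.83 became 0 at an adjusted p of 0.01, where 6 lower genes were left. A gene window of 5 kb gave odds ratios of 14.5 for higher genes with a gain and 4.50 for lower genes with a loss. Control peaks shared with knockouts (105447) numbered 83947 with an overlap of at least 50% of both peaks and 77693 at a q below 0.001.

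For single cells, keeping cells with at least 500 genes changed the erythroid-like share from 0.140% to 0.557% in the control and from 0.321% to 0.948% in the knockout, the mesenchyme-like share from 67.8% to 64.2% and from 65.3% to 57.6%, and the knockout mural-like share from 1.98% to 3.58%. Doubled resolution gave mesenchyme-like shares of 60.0% and 51.5%, a knockout mural-like share of 5.30% and a control endocrine-like share of epithelium-like cells of 17.3%. Doublets kept gave 17.3% for the latter, 2.56% for endocrine-like cells among all control cells, and mural-like shares of 4.01% and 2.81%. Clustering without genes that differed between libraries gave 17.2% and, for knockout mural-like cells, 2.84%. The cause of the changed shares was not tested, though clusters without a name held 176 cells with at least 500 genes and 352 at doubled resolution.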

Other observations

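Tests of Eed loss acting on chromatin, of expression by knockout mesenchyme, and all 3 tests on endocrine and exocrine differences were chosen after the results were seen, and before the test of a background variant the values of Eif3j2, Wdfy1, Trim12a and Cdkn2a in each class, though not the medians, had been seen. Mesothelium-like cells, where Cdkn2a reached 95.1 CPM in the knockout, changed in other genes as well. With 1 library per genotype, 3 of 5 HoxC genes had a higher level there (median log2 ratio 1.45, percentile 99.99 among random lists), as did 3 of 13 anterior Hox genes (-0.53, below all random lists), 16 of 24 matrix genes (0.33, percentile 100), 6 of 8 mesothelial markers (0.38, percentile 99.95) and 8 of 22 proliferation genes (-0.22, percentile 0.06). Klk13 had 220 UMIs in control and 7 in knockout mesothelium-like cells, Rprm 386 and 43, and C1ql2 50 and 0 (at least 15.2-fold lower). The mesenchymal factor Osr2 rose in both classes, from 5 to 68 UMIs in mesothelium-like cells and from 54.2 to 184 CPM in mesenchyme-like cells. Mesenchyme-like cells also had less of the growth factor gene Nrg1 (234 and 16 UMIs) and of Elovl7 (108 and 8 UMIs). Chosen after their values were seen, Hand2 went from 223 to 143 CPM and Sfrp1 from 840 to 467 CPM in mesenchyme-like cells.

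Among mesenchyme-like clusters with cells of both genotypes, the cycling ones also expressed Cdkn2a in the knockout. In the cluster with the highest Mki67 level (241 CPM in control and 260 in knockout cells), Cdkn2a had 1 and 116 UMIs and Pitx1, a hindlimb factor, 0 and 32 UMIs (at least 20.8-fold higher). Crabp1 rose from 73.0 to 230 CPM there, and Osr2 from 54.3 to 189 CPM. In a further cycling cluster (Mki67 at 209 and 249 CPM) Cdkn2a had 0 and 59 UMIs (at least 37.9-fold higher). The former cluster held 145 control and 70 knockout cells and the latter 125 and 67, of 1448 control and 1219 knockout mesenchyme-like cells. The clusters were formed from the same counts, so their similar Mki67 levels follow in part from how cells were grouped. Regions with counts in 1 genotype alone in all 3 organs were looked at first and not weighed, since sharing between organs does not separate a variant from loss of Eed.

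Genes that changed in knockout mesenchyme may reflect loss of Eed in Cre-expressing cells, or a variant of the genetic background that all cells of the knockout embryos carry. A variant that acts in every cell type would change the same genes in epithelium-like cells. Of 321 genes higher in bulk RNA, 27 had enough counts in both mesenchyme-like and epithelium-like cells. Their median log2 ratio in epithelium-like cells was 0.18 (-0.0038 to 0.42), against 1.26 in mesenchyme-like cells. Of 72 lower genes, 11 had enough counts, with a median of -0.11 (-0.48 to 0.26) against -0.98. For these 27 and 11 genes as sets, such a variant is argued against as the source, by a narrow margin for the lower ones. The intervals cover genes and not libraries, with 1 library per genotype. The test does not reach the other called genes, or a variant that acts in mesenchyme alone. Single genes stay open, such as St6galnac2, the 1 with a 2-fold rise in epithelium-like cells, and genes outside the bulk calls did fall in all these classes: Tpm3-rs7 (1499 and 52 UMIs in mesenchyme-like, 345 and 6 in acinar-like, 413 and 16 in trunk-like cells), Hist1h2ak (1026 and 49, 267 and 28, 235 and 23) and BC023719 (320 and 1, 50 and 0, 54 and 0). Loss of Eed stays open. The odds ratio of 13.4 for higher genes with gained regions (9.17 to 19.4) was known before it was set as a test. PRC2 marks were not measured. Sex differed among the bulk RNA libraries but did not follow genotype. Ddx3y was at 47.8 and 99.3 CPM in controls, between 128 CPM in knockout replicate 1 and 0 CPM in knockout replicate 2. These values argue against sex as the source of the 393 called genes, which had no overlap between genotypes.

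Endothelial genes that were higher in knockout bulk RNA may come from endothelial cells carried along in the knockout sorts, since the labels name no gate that would remove them. Over 10 genes specific to endothelium-like single cells and absent from the marker list the median log2 change was 2.19 (1.82 to 2.52), against 2.65 for called list members and 2.22 for the whole list, and 9 had an estimate of at least 2-fold, of which Icam2, Ctla2a and Gimap1 missed the threshold (adjusted p 0.0511, 0.0686 and 0.166), with Aplnr at 5.13 and 22.9 CPM, Clec14a at 5.40 and 15.9 CPM and Fabp4, the most abundant in these cells, at 0.699 and 4.03 CPM. For expression by the mesenchyme itself, called list members together had 82 UMIs in control and 51 in knockout mesenchyme-like cells, a ratio of 0.757 (0.523 to 1.09) against a smallest bulk fold of 4.46, while of the 10 genes some were higher there, such as Clec14a (1.35 and 3.76 CPM), Rasip1 (2.06 and 3.69 CPM) and Lmo2 (0.487 and 1.65 CPM), and 1 library per genotype leaves it open. The criteria asked for 30 genes and 10 met them. More endothelium in the knockout organ was not seen, as endothelium-like cells made up 1.22% and 0.857% of cells, with 1 library each.

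Endocrine-like cells were more frequent in the knockout single-cell library. The digestive enzyme genes Ctrc and Cela2a were higher there in acinar-like cells and Ctrb1 in trunk-like cells. Digestive enzymes were not tested as a list, and pancreatic epithelium markers were higher in mesenchyme-like cells too (median log2 ratio 0.74). The differences in epithelium-like cells could come from older embryos, from lower recovery of other epithelial cells, or from mesenchyme acting on the epithelium. Endocrine-like cells made up more of all cells as well (4.71%, 3.80 to 5.78, against 1.87%), but these intervals cover cells and not libraries, so recovery stays open. Older embryos cannot be told apart from genotype, and this holds for mesenchyme-like cells of these libraries as well. The embryonic globin Hbb-y made up 1.66% of beta-globin counts outside erythroid-like cells in the knockout against 29.6% in the control. Each class outside the erythroid-like one had a lower share in the knockout, at 0% to 2.67% against 27.8% to 36.0%. The opposite direction, 10.0% against 0.0142%, came from 6 knockout and 3 control erythroid-like cells. Over all cells, the form tested first, the knockout had 8.72% and the control 6.03%, a total that the 9 erythroid-like cells dominate. In bulk RNA, Hbb-y made up 1.52% and 15.1% of the counts of Hbb-y, Hbb-bs and Hbb-bt in controls. In knockouts it made up 100% and 62.5%, a higher share than in controls, from only 5 and 64 counts. Embryo age was not tested for the bulk libraries. An effect of the mesenchyme, with 28.9% of epithelium-like cells endocrine-like against 12.8%, stays open too, as 1 library per genotype separates it neither from age nor from sex.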
